A study of Bos taurus with 10 samples.

How the data were processed

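RNA was sequenced from 5 articular cartilage and 5 acetabular labrum samples of cattle, each kept in growth medium for 2 days before extraction. The deposited files hold whole-number read counts per gene, 1 file per library, with 23819 genes each. Per the submitters' processing notes, STAR and featureCounts were used to align and count the reads. Their versions, the genome build, the annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Genes that overlap or resemble another gene can share reads under such counting, and without names these could not be singled out.

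Libraries were grouped by the tissue in the labels, and replicate numbers were taken from the sample titles. Total counts were 3958167 in the shallowest library, labrum replicate 3, and 27043808 in the deepest, cartilage replicate 5. Of all genes, 6532 had 0 counts in all 10 libraries. Pairs of libraries from one tissue differed by more than sampling noise. The smallest chi-square per degree of freedom over the 20 pairs was 13.2, for genes with at least 20 counts in the pair, so all libraries were kept as separate replicates.

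Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with the default filter, which left 12333 genes holding 99.88% of all counts. Libraries were scaled by TMM, with mean factors of 0.919 in cartilage and 1.09 in labrum. A quasi-likelihood model with tissue as the only term was fitted with robust dispersion estimates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are labrum relative to cartilage. Values in CPM use TMM-scaled library sizes, except for genes present in only one tissue, which use library totals, and log2 CPM use a prior count of 2. On counts simulated for the same 12333 genes with 50 genes changed at each size, the test recovered 2% at 1.25-fold, 22% at 1.5-fold, 84% at 2-fold and 98% at 4-fold. Of its 106 calls, 3 (2.83%) were false. The 200 changed genes were drawn only from genes above a minimum mean count. In the real comparison 7738 genes passed, which makes the adjusted threshold less strict, so these rates do not carry over to it.

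The gene identifiers were looked up in the RefSeq gene table, and 0 of 23819 matched, because 0 of the 37063 entries of that table hold an Ensembl identifier. The 31 gene lists written before the data were examined were therefore not tested, and no gene is named. The rule for named genes, also fixed then, took genes past the test with no overlap between tissues and a mean of at least 10 CPM in the higher tissue, in order of fold change. Without its condition on gene symbols, 2375 higher and 2418 lower genes met it. The first 2 in each direction are given by identifier, which is fewer than the rule had fixed. For a gene with 0 counts in one tissue, the fold is a bound against 3 counts over the 5 libraries of that tissue, and with a few counts the ratio of pooled counts is given with an exact 95% binomial interval. Both use TMM-scaled library totals, and bounds are rounded down. Intervals and floors cover counting error only.

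Genes detected were computed at the depth of the shallowest library as the hypergeometric expectation. Library measures were compared by exact two-sided permutation tests over the 252 arrangements of the 10 libraries, adjusted over 5 measures. The library measures, the genes present in one tissue only and the 16-fold class were chosen after the data were examined. Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma 3.58.1 with voom, a 1.5-fold test, a stricter threshold, the replicate number as a block, removal of the 20 most abundant genes, and removal of each library in turn.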

Results

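Gene expression was measured by RNA sequencing in 2 bovine joint tissues, the articular cartilage and the acetabular labrum. The articular cartilage covers the bone ends of a joint, and the labrum is the fibrocartilage rim of the hip socket. All tissue came from male animals without visible disease and was kept in culture medium for 2 days before RNA was extracted. Each tissue was represented by 5 libraries, which the labels number 1 to 5. The labels do not say whether these came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical. Total counts per library ranged from 7910479 to 27043808 in cartilage and from 3958167 to 19179862 in labrum. The labels do not give the joint or surface from which the articular cartilage was taken, so the comparison of tissues includes any difference between sites. The question addressed was how the baseline transcriptome of the labrum differs from that of articular cartilage. The files identify genes by Ensembl number and do not pair these with gene names, so genes are described below as groups and 4 are given by identifier.

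Expression profiles were alike within a tissue and differed between the tissues. Across genes, the correlation of log2 CPM (read counts scaled to a common library size) was 0.953 to 0.981 between cartilage libraries and 0.953 to 0.984 between labrum libraries. Between a cartilage and a labrum library it was 0.713 to 0.77. Genes are not independent replicates, so these coefficients describe similarity only. The first principal component held 83.6% of the variance and placed all 5 labrum libraries on one side and all 5 cartilage libraries on the other. The second component held 4.31%.

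**Figure D1:**
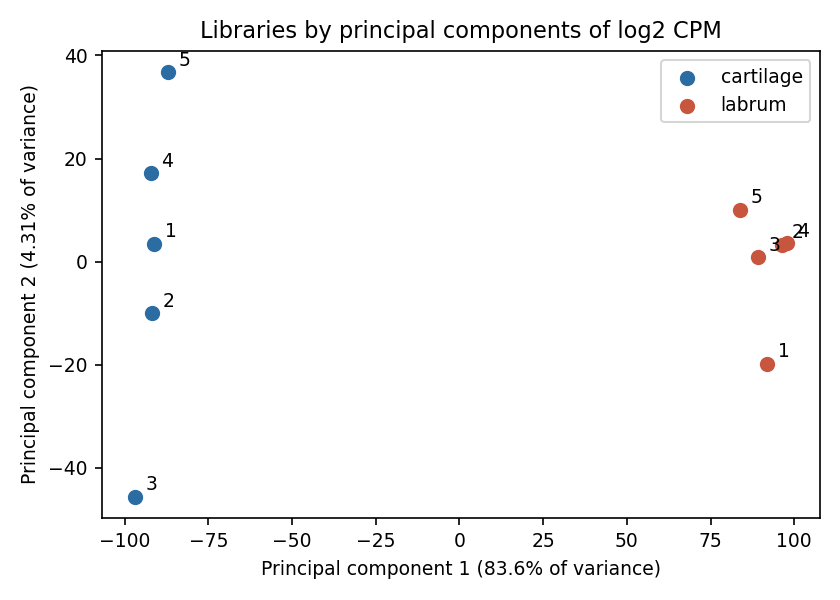
Position of the 10 libraries on the first and second principal components of log2 CPM, with the percentage of variance on each axis and the replicate number beside each point. Cartilage libraries lie between -96.89 and -87.1 on the first component and labrum libraries between 83.82 and 97.88.

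Most expressed genes differed in abundance between labrum and cartilage. Of 12333 genes tested, 3877 were higher and 3861 were lower in labrum (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 5 per tissue). Together these were 62.74% of the genes tested. Among them, 1859 genes were at least 2-fold higher and 1871 at least 2-fold lower in labrum. In 3030 of the higher genes every labrum library lay above every cartilage library, and in 2885 of the lower genes every labrum library lay below. Such separation was seen in 48.24% of all tested genes, against 0.794% by chance. For 3215 of all tested genes the 95% confidence interval of the fold change lay within 1.5-fold in either direction. Some of these also passed the test, so they overlap with the genes that differed. The balance of higher and lower genes depended on scaling. With library totals alone, the median log2 fold change of all genes moved from near 0 to 0.25, and 5154 genes were higher and 2588 lower, so directions are relative to the TMM scaling.

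**Figure D2:**
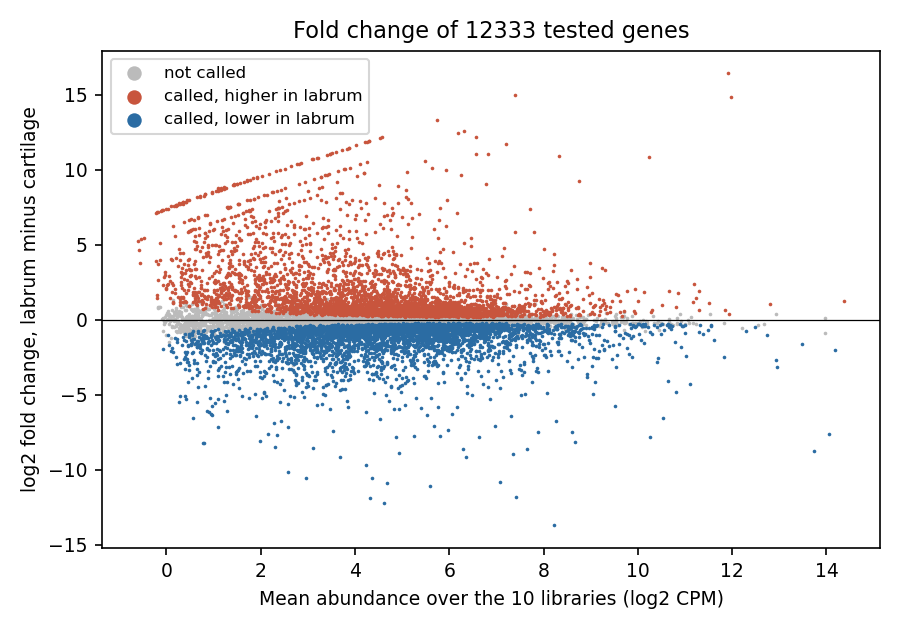
Log2 fold change (labrum minus cartilage) of each tested gene against its mean abundance in log2 CPM, with genes past the adjusted p threshold coloured by direction. Among these, 3877 lie above 0 and 3861 below, and the straight lines of points at the top are genes with few or no counts in cartilage.

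The largest differences were more often in the direction of labrum. Among the genes that passed the test, 491 were at least 16-fold higher in labrum and 163 at least 16-fold lower. Between 4-fold and 16-fold the numbers were 562 higher and 580 lower. Between 2-fold and 4-fold they were 806 higher and 1128 lower, and 2018 higher and 1990 lower genes differed by less than 2-fold. Fitted fold changes of genes near 0 counts depend on the prior count, so the largest class was also counted from pooled counts with a floor of 3 counts over the 5 libraries of a tissue. By that measure 495 genes were at least 16-fold higher and 167 at least 16-fold lower in labrum with TMM-scaled totals, and 541 and 138 with library totals alone. Without a filter on low counts the fitted numbers were 843 and 302, and with DESeq2 they were 829 and 271.

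**Figure D3:**
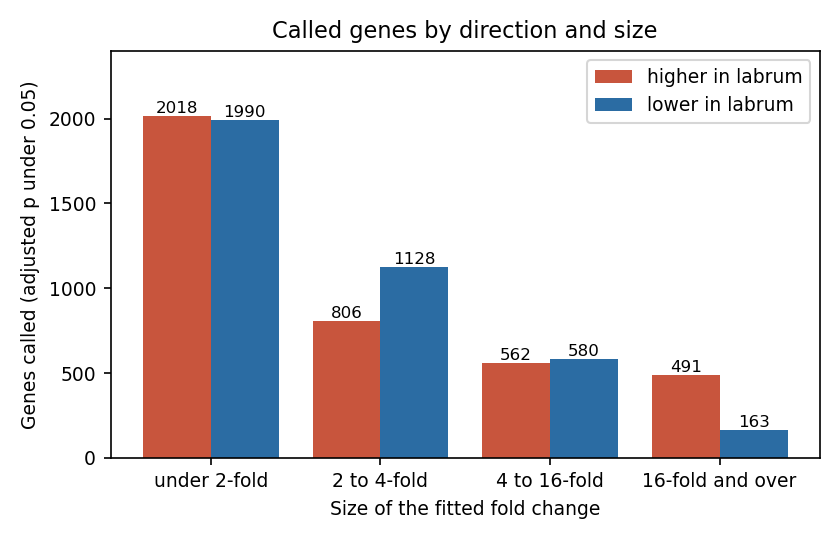
Number of genes past the adjusted p threshold in each class of fitted fold change, higher (red) or lower (blue) in labrum. The class of 16-fold and over holds 491 higher and 163 lower genes.

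Genes that differed at least 2-fold made up a large part of the RNA of each tissue. Those higher in cartilage took 30.8% ± 2.5 of cartilage counts and 7.62% ± 0.703 of labrum counts (SD, n = 5 each). Those higher in labrum took 20.1% ± 1.45 of labrum counts and 4.57% ± 0.234 of cartilage counts (SD, n = 5 each). These genes were chosen on the same libraries, so the shares describe their size and are not a separate test. The median coefficient of variation between libraries, over such genes at 10 CPM or more, was 19.9% in labrum for its 1176 genes and 20.3% in cartilage for its 1382 genes.

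The most abundant transcripts were partly shared. Of the 20 most abundant genes of each tissue, 13 were the same, and of the 100 most abundant, 70 were the same. Among the 20 most abundant genes of cartilage, 12 were lower in labrum, 10 of them at least 2-fold, and 2 were higher. Among the 20 most abundant genes of labrum, 9 were higher in labrum, 7 of them at least 2-fold, and 5 were lower. The most abundant gene of labrum took 3.25% ± 1.18 of labrum counts and 1.1% ± 0.457 of cartilage counts (SD, n = 5 each), and ranked first in all 5 labrum libraries. The most abundant gene of cartilage took 2.94% ± 2.21 of cartilage counts and 0.0184% ± 0.0142 of labrum counts (SD, n = 5 each), and ranked first in 2 of the 5 cartilage libraries. Both genes were singled out after their values were seen.

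Some genes were detected in one tissue and were nearly absent from the other. A total of 184 genes reached 1 CPM in every labrum library and had at most 3 counts over the 5 cartilage libraries together. The reverse held for 30 genes. The 3 counts correspond to 0.0427 CPM over the cartilage libraries and 0.0562 CPM over the labrum libraries. The median level in the expressing tissue was 7.01 CPM for the labrum genes and 5.43 CPM for the cartilage genes. With 0 counts required in the other tissue, the numbers were 80 and 6. With at least 5 CPM required in each library of the expressing tissue, they were 70 and 9.

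The gene ENSBTAG00000013103 was measured at 7718 ± 3598 CPM in labrum (SD, n = 5), with 5 counts in all cartilage libraries together. The ratio of pooled counts over TMM-scaled totals was 106000, with a 95% counting interval of 45600 to 328000 (edgeR adjusted p = 4.55e-09). Without cartilage replicate 5, which held most of those few counts, the ratio was 348000. The gene ENSBTAG00000004207 was measured at 335 ± 61.14 CPM in labrum (SD, n = 5) and had 0 counts in cartilage. It was at least 7390-fold higher in labrum against the floor of 3 counts over the group (edgeR adjusted p = 1.86e-08). Without cartilage replicate 5 that bound was 4820.

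In the other direction, ENSBTAG00000018843 was measured at 594.7 ± 714.8 CPM in cartilage (SD, n = 5), with 2 counts in all labrum libraries together. The ratio of pooled counts, scaled in the same way, was 23500, with a 95% counting interval of 6510 to 194000 (edgeR adjusted p = 2.17e-06). Cartilage replicate 5 decided its mean, which was 277 ± 92.18 CPM without that library (SD, n = 4). The ratio was 7320 without cartilage replicate 5, 14900 without labrum replicate 4, 43300 without labrum replicate 3 and 37400 without labrum replicate 5. The gene ENSBTAG00000025502 was measured at 48.75 ± 35.57 CPM in cartilage (SD, n = 5) and had 0 counts in labrum. It was at least 1000-fold lower in labrum against the same floor (edgeR adjusted p = 0.000304), a bound that was 835 with library totals alone, 648 without cartilage replicate 5 and 636 without labrum replicate 4. Intervals and floors cover counting error only.

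Labrum libraries held more kinds of transcript at equal depth. When every library was thinned to 3958167 counts, the number of genes detected was 13977 ± 106 in labrum and 13368 ± 155 in cartilage (SD, n = 5 each). The difference of 609.5 genes had an exact permutation p = 0.00794, two-sided, and p = 0.0198 adjusted over 5 measures. That permutation p of 0.00794 is the smallest this design can give with the libraries taken as unpaired. If the replicate numbers pair the samples, an exact two-sided test over 5 pairs could not go under 0.05. The p-values of all library measures therefore hold only for unpaired libraries. All 5 labrum libraries lay above all 5 cartilage libraries. At each library's own depth the difference was 326.4 genes (exact permutation p = 0.31, adjusted p = 0.388). The number of genes that together held 50% of the counts was 421 ± 74.5 in labrum and 264.8 ± 77.5 in cartilage (SD, n = 5 each; exact permutation p = 0.00794, adjusted p = 0.0198), again without overlap. The 10 most abundant genes took 12.24% ± 2.57 of labrum counts and 17.48% ± 4.05 of cartilage counts (SD, n = 5 each; exact permutation p = 0.0556, adjusted p = 0.0927). The unadjusted p was 0.0476 when cartilage replicate 1, labrum replicate 1 or labrum replicate 5 was left out. Total counts did not pass the test (exact permutation p = 0.468).

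**Figure D4:**
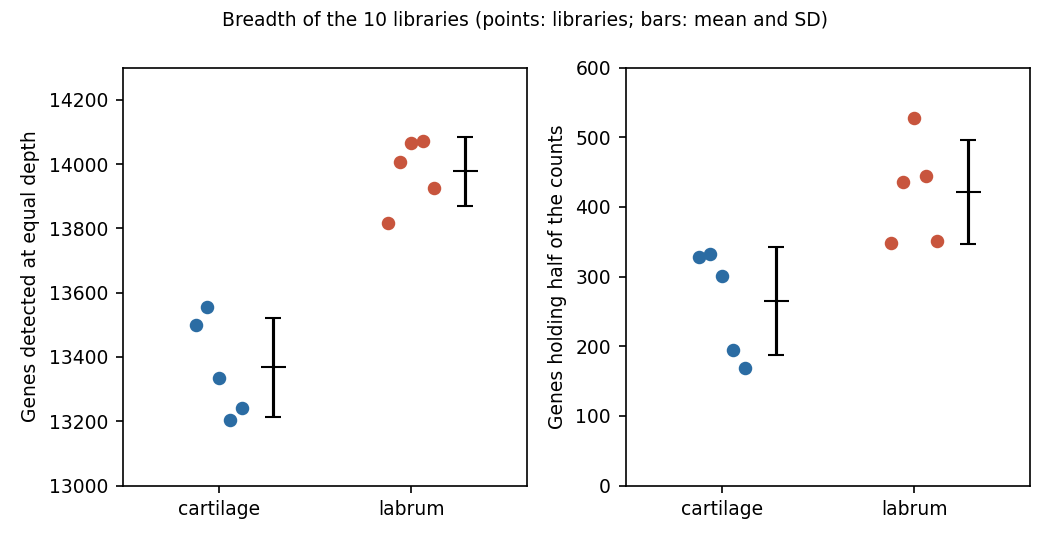
Genes detected at equal depth (left, axis not from 0) and genes that together hold 50% of the counts (right) in each library, with points for libraries and bars for the mean and SD of 5. In both panels all labrum points lie above all cartilage points.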

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

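The level of ENSBTAG00000018843 in cartilage replicate 5 was 1865 CPM, while the next highest cartilage library was at 401.9 CPM. That gap was 0.87 of the range of the 5 libraries, above the critical value of 0.71 for a single value far from the others. Of 24 groups of values examined this way, 1 gave such a value, and chance gives about 1 in 20. No explanation of it was tested.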

How the results depend on the processing

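The 16-fold class, the genes present in one tissue only and the library measures, with their alternatives, were chosen after seeing the data. Over all results and alternatives, 239 values stayed on their side of the threshold or within 1.5 times, 8 moved further, 3 passed the threshold, 1 no longer did (library measures by their unadjusted p), and 0 reversed. Each direction was judged alone, so the 239 include the change of balance with library totals alone. There 5154 genes were higher and 2588 lower in labrum, and 2428 and 1447 were so by at least 2-fold. The 8 were the 16-fold counts without a filter (843 higher, 302 lower) and with DESeq2 (829 and 271), and the genes present only in labrum or only in cartilage with 0 counts allowed in the other tissue (80 and 6) or at least 5 CPM (70 and 9). The cause was not tested. Detected genes without thinning differed by 326.4 (exact permutation p = 0.31), where library depths differ. Leaving out each library in turn gave 3577 to 3964 higher and 3554 to 3882 lower genes, 568.7 to 656.7 for detected genes and 129.7 to 174.4 for genes holding 50% of counts. For the share of the 10 most abundant genes the difference was -6.076 to -3.981 percentage points, and its unadjusted exact permutation p, 0.0556 with all libraries, was 0.0476 without cartilage replicate 1, labrum replicate 1 or labrum replicate 5. Between 4.73% and 8.54% of calls were lost with a library left out, and 0 changed sign. With the replicate number as a block, 3842 genes were higher and 3766 lower, 346 calls were lost and 0 changed sign. Same-numbered libraries deviated together with a mean correlation of 0.156, the highest of 120 pairings (exact permutation p = 0.00833, one-sided), and 8 of 10 libraries correlated best with their own number. The correlation ran from 0.091 for number 3 to 0.25 for number 2. The labels do not say that equal numbers mean 1 animal, so this is a hint from the data that the numbers pair samples, not the design. The 4 identifiers kept their direction and call in every alternative that tested them. The planned gene list tests, with camera and fry, were not run because the gene table used held no Ensembl identifiers to pair with names. The shallowest library, at 3958167 counts, limits the detection of rare transcripts.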

Other observations

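The patterns weighed here were noticed in the data first, and the test for cartilage RNA in labrum replicate 5 was also chosen only after its result was seen. Of 100 splits of the 10 libraries into 5 and 5, only the real one, with 7738 genes, gave as many genes, so 1 of 100 splits did. The highest of the others gave 0 genes past the adjusted threshold with edgeR and 3535 at an unadjusted p under 0.05, against 8163 in the real split. Each other split placed between 1 and 4 labrum libraries in each group, so the tissue difference entered its residual spread and lowered its count. The lead of the real split therefore repeats the grouping of libraries by tissue. It is no separate evidence against chance, and the count of 0 adds nothing on the size of the difference.

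Labrum libraries held more kinds of transcript at equal depth, and 184 genes were present only in labrum against 30 only in cartilage. The difference of 609.5 detected genes was defined at equal depth, so it is not a separate test of depth. Pooled cartilage counts were the deeper, at 70332792 against 53399268 in labrum, which makes absence from cartilage harder to reach. With pooled depths made equal, genes present only in labrum were 7 times those only in cartilage. Depth is thus argued against for these unequal numbers. The 20 most abundant genes are argued against as the whole cause of the higher number of detected genes. Without them the difference was 538.8, with the lowest labrum library at 13851 and the highest cartilage library at 13612. Counts were still more concentrated in cartilage, where 123.8 fewer genes than in labrum held the same share of counts without those 20. Uneven shares spread over more genes were not tested as a cause and stay open. Cartilage RNA carried into labrum libraries is argued against as the whole cause of the unequal numbers of genes present in one tissue only, since removing even 0.567%, the highest upper limit found for any labrum library, would raise those only in cartilage to 51, which is 27.7% of 184, but it was not tested as a cause of the higher number of detected genes and stays open there. A wider range of cell types in the labrum remains a candidate explanation that was not tested, because no gene was paired with a name.

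Labrum replicate 5 lay nearest to cartilage, with a mean correlation of 0.7582 against 0.7246 to 0.7407 for the other labrum libraries, although one of 5 must be nearest. A first test of cartilage RNA in it did not decide, since it gave 2.02% over moderately different genes while the other libraries ranged from -3.25% to 4.82%, and it was replaced. Genes absent from the other labrum libraries allowed 0.0961% (bootstrap interval 0.0379 to 0.23), which at its upper end would move a gene 16-fold apart by 3.45%. Over genes under 16-fold apart the correlation of labrum replicate 5 was still highest at 0.8566. Its lead of 0.0103 had a bootstrap interval over genes of 0.00739 to 0.0131, wholly positive, which met the written criterion. That lead was smaller than the range of 0.0128 among the other 4 labrum libraries. This bound lay outside the written criterion, and because of it mixed RNA was left open for labrum replicate 5. After thinning to equal depth its correlation was 0.7813 and still highest, against 0.7516 to 0.7697 for the other labrum libraries. Its lead fell from 0.0175 to 0.0116, less than the largest shift of 0.029 that thinning made in a labrum library. That shift was the bound set beforehand. Thinning raised all 5 labrum libraries, so the bound is largely a shift common to them and says little on their order. Depth remains open by that bound, although the remaining lead was seen at equal depth. A difference between animals or in the site of sampling may also remain, and was not tested.

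Genes listed next to each other had more similar fold changes than genes in random order, with a Spearman rho of 0.143 across genes against at most 0.0297 in 1000 permutations; genes are not independent replicates, and the order is that of the files, with no coordinates used. Reads shared only between directly adjacent genes predict no correlation beyond the nearest genes, but it was 0.0717 at 2 places and 0.0321 at 3 to 5 places. The latter lay above all permutations, which reached 0.018, and above all 117 windows of 3 distances between 50 and 400 places, which reached 0.0211 and were added after the result was seen, so reads shared by adjacent genes are argued against as the whole cause, although single distances gave 0.0157 at 20 places and 0.0289 at 100 places, the latter close to the value at 3 to 5 places. Reads shared over several places, as between genes that resemble each other, were not tested as a cause and stay open. Splits of libraries within one tissue gave a median rho of 0.0933 and at most 0.222 between adjacent genes. At 3 to 5 places they gave a median of 0.0559 and at most 0.132. A bias along the listing that varies between libraries can thus give values as high, and stays open as a cause. No biological explanation was tested.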
